A study of Peromyscus maniculatus nubiterrae and Peromyscus maniculatus bairdii with 35 samples.

How the data were processed

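Per the labels, total RNA was extracted from embryonic tails and polyadenylated RNA was made into sequencing libraries, for 18 forest and 17 prairie samples. Per the submitters' processing notes, cutadapt 1.13, STAR 2.5.3 and RSEM 1.3.0 were used by the authors. These tools trim reads, align them and estimate the abundance of each transcript. The genome build and annotation that the authors used are not given in the sources used here. The deposited table has 38 columns of values and 46636 features.

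Apart from a look at the column totals and the range of the values to learn their unit, only the names of the columns and features were analysed. Each column's prefix and barcode were sought as whole words in the labels, and each feature identifier was sought as a whole entry in a table of gene names for P. m. bairdii. All 38 columns were left out, because none was matched to a sample or to a group of ecotype and stage. Because unmatched columns were not used, the depth per column is not reported, and no normalization or test was run.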

Results

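Embryonic tails of 2 subspecies of the deer mouse, Peromyscus maniculatus, were profiled by sequencing polyadenylated RNA. P. m. nubiterrae was labelled as the forest ecotype and P. m. bairdii as the prairie ecotype. The early stage covered E12.5 to E13.5 and the late stage E14.5 to E15.5, in days of embryonic development. The labels list 7 early and 11 late forest samples, and 11 early and 6 late prairie samples. The design implies a comparison of the ecotypes at each stage, of the stages within each ecotype, and of the ecotype difference between the stages.

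None of these comparisons was made, and no expression level, fold change or test is reported. The deposited table has 38 columns of values, each named by a prefix and a sequencing barcode. The prefix was BW in 17 columns and NUB in 21 columns. Of the 38 columns, 0 carried a prefix or a barcode that occurs as a whole word in the labels, and 0 carried a stage. NUB is the start of the subspecies name nubiterrae, so the whole-word rule could not count it as a match to that name. If BW is read as the prairie ecotype, its 17 columns equal the 17 prairie samples in number. If NUB is read as the forest ecotype, its 21 columns outnumber the 18 forest samples by 3, and the labels do not say which columns are the listed samples. A comparison of the prefixes alone was not made, because it could include columns of no listed sample or repeats of a listed sample. It would also mix the stages in unequal parts, since 7 of the 18 forest samples and 11 of the 17 prairie samples are early. No column was dropped or given a stage by its values.

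The table has 46636 features, of which 45370 have an identifier that starts with DEERMOUSE_G and 1266 an identifier that starts with APOLLO. In the gene table used here, 0 of the 46636 identifiers were found. The posterior Hox genes, the tailbud, cartilage and muscle markers and the other gene lists that were fixed before the data were examined were therefore not analysed here.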

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

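All alternatives reported here were chosen after seeing the data, and they concern the names of columns and features only, since no expression value entered a comparison. With the prefix read as the start of a word in the organism name, 21 columns were tied to an ecotype. With the prefix also sought in the name of the assembly given in the gene table used here, 38 columns were tied to an ecotype. The sources used here do not say whether the authors used that assembly. Under both readings 0 columns were tied to an ecotype and a stage. No reading of the prefix could change this count, because no column name carries a stage. Ignoring case left 0 identifiers found in the gene table. No paired analysis was possible because the column names carry no replicate number, and the labels only number the samples within each group and tie no number to a litter, batch or day. None of the alternatives for normalization, filters and tests that were planned before the data were examined was run.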
